A study of Mus musculus with 8 samples.

How the data were processed

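RNA was measured by sequencing in 8 thymic lymphomas of p53-null C57BL/6 mice. The mice were 10 weeks old when an adenovirus was injected into the tumour, and the tissue was collected 48 hours later. Per the labels, 2 control tumours (ΔNfl/fl;p53-/-) received a virus with mCherry alone (Ad-mCherry), 3 tumours labelled ΔNp63Δ/Δ;p53-/- and 3 labelled ΔNp73Δ/Δ;p53-/- received a virus with Cre recombinase and mCherry (Ad-CRE-mCherry). ΔNp63 and ΔNp73 are the forms of p63 and p73, relatives of p53, that lack the N-terminal transactivation domain. The labels give no replicate numbers, pairs, batches or sex, and nothing in them shows that the libraries of a group come from separate animals, so p-values measure only the spread between samples. The groups are named here by their labels, as the ΔNp63-labelled and ΔNp73-labelled groups, and replicates are numbered in the order of the labels.

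The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled by library size) per RefSeq transcript, quantile-normalised between the 8 libraries. Per the labels, TopHat2 2.0 and Cufflinks 2.0 were used with the mouse build mm9; which step each tool served is not stated. The table holds 16589 transcript entries under 13681 symbols, 2113 of which have more than 1 entry. The sorted values of all libraries were equal within 1% except in the lowest 2366 entries (14.3%). Entries may have been left out after the normalisation, though no rule for it is stated and this was not tested. The depth of the libraries is unknown, since the table holds no counts, and no counting interval or detection limit is given. The normalisation gives every library the same distribution, so a change in the total amount of RNA cannot be seen. Symbols turned into dates (35 entries) were restored from the RefSeq identifier, and 770 entries carry an identifier in place of a symbol.

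A single entry per symbol was kept, that with the highest mean over all libraries. Genes with an FPKM of at least 1 in at least 2 libraries were tested (12921 genes). Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided), with all 8 libraries in 1 model with 5 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all genes tested in a comparison, with a threshold of 0.05. The comparisons were each deletion group against control, the mean of both against control, and ΔNp73-labelled against ΔNp63-labelled. Log2 fold changes (log2FC) are given with their standard error (SE), and group means of FPKM with their standard deviation (SD). Genes changed in both comparisons with control were counted by direction and set beside the overlap of independent lists and 100 simulated draws of unchanged groups against shared controls. In each draw all libraries, controls included, were redrawn around the gene's mean with the same spread per gene.

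A total of 34 gene lists was fixed, of which 28 had at least 5 measured members and were tested. The lists on the study's question were targeted genes, amylin and its receptor, p53-family target genes, intrinsic and extrinsic apoptosis, senescence, glycolysis, the TCA cycle and oxidative phosphorylation, inflammasome and reactive oxygen species, proliferation, MYC and E2F-linked growth, the Notch pathway, interferon response, hypoxia, epithelial and p63-linked genes, and microRNA processing. The lists for cell types were thymocytes and T cells, B cells, cytotoxic lymphocytes, macrophages and monocytes, neutrophils, dendritic cells, erythroid cells, platelets and megakaryocytes, fibroblasts and stroma, endothelium, thymic epithelium, skeletal and heart muscle, adipocytes, lung and airway epithelium, and pancreas. Immediate early and heat shock genes, ribosomal proteins, replication-dependent histones and sex-linked genes stood for handling of the tissue and the sex of the mice. Some genes belong to more than 1 list. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were run as alternatives. The number of members past the threshold over all genes is given beside the number adjusted over the list alone.

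The named genes were Trp53, Trp63, Trp73, Iapp, Calcr and Ramp1 to Ramp3; per direction the 10 genes with the largest change among those past the threshold whose groups do not overlap (5 for the comparison of the deletion groups), filled up to 5 with the smallest p where fewer passed; and up to 4 members of each called list and of the lists on p53 targets, apoptosis, senescence, glycolysis and thymocytes. Small RNA genes, gene models without a descriptive symbol and antigen receptor segments were counted but passed over. Some genes that the rule names are not reported here. Genes outside the rule are named as chosen after their values were seen. The comparisons, test, filter, lists, named-gene rule and alternatives were chosen before the data were examined.

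The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, centring on library medians, equal totals, a model of the compared groups alone, empirical Bayes without trend or robust, limma's array weights, summed entries per symbol, adjusted p under 0.1, a further threshold of 2-fold, and leaving out each library. The model was tested on simulated data of the same size with 200 changed genes: of the 50 genes with a simulated log2 change of 2, it recovered 82% in the ΔNp63-labelled comparison, 72% in the ΔNp73-labelled comparison, 78% in their mean and 76% between the deletion groups. With a simulated log2 change of 1 it recovered 30%, 34%, 38% and 36% in that order, and it made 13, 8, 5 and 7 false calls. Without ΔNp63-labelled replicate 2 the figures were 94%, 96%, 98% and 96% for a change of 2 and 62%, 74%, 82% and 86% for a change of 1, with 7, 13, 12 and 14 false calls. Of simulated lists, 30 of 30 shifted and 0 of 30 unshifted ones were called. Each simulated gene was drawn independently, so this does not test for false calls that come from correlation between the genes of a list.

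Transcript starts, gene neighbours and chromosomes came from GENCODE and RefSeq for the assembly GRCm38, matched by RefSeq identifier or symbol. That is a later build than mm9, so no coordinates are given. Neighbours were taken as of unrelated name by the first letters of their symbols alone. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Trp73 and Calcr were not analysed here, so the ΔNp73 label was not checked.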

Results

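Expression was measured as quantile-normalised FPKM in 8 mouse thymic lymphomas lacking p53: 2 controls given Ad-mCherry, 3 libraries labelled ΔNp63-deleted and 3 labelled ΔNp73-deleted, both given Ad-CRE-mCherry. The design asks how loss of each ΔN form changes the transcriptome of a p53-null tumour 48 hours after the virus. The control differs from both other groups in the virus as well as in the genotype, so the effects of Cre and of a deletion are not separated in any comparison with control. The control label, ΔNfl/fl, does not say which of the genes is floxed. The depth of the libraries is unknown.

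The targeted gene Trp63 had 4 transcript entries, all of which start at the ΔN promoter in the annotation. Its highest entry was at 5.21 and 3.38 FPKM in the controls, at 6.57, 1.05 and 9.91 in the libraries labelled ΔNp63-deleted and at 13.8, 11.3 and 6.38 in those labelled ΔNp73-deleted. That entry did not differ by the test in the ΔNp63-labelled group (log2FC 0.09, SE 0.67, adjusted p = 0.973), nor without replicate 2 of that group (0.80, adjusted p = 0.144). The other 3 entries were not tested. Their means were lower in the ΔNp63-labelled group than in control, at 3.47 against 5.41, 2.21 against 4.12 and 0.636 against 0.850 FPKM, with libraries that overlap in each. These values do not settle whether ΔNp63 was lost. FPKM per transcript is a weak check of a deletion, since the transcripts share most exons. Directions given below rest on the labels. Trp53 was still measured, at 81.0 and 67.6 FPKM in the controls, at 17.3, 16.1 and 46.3 in the ΔNp63-labelled libraries and at 66.1, 75.9 and 10.96 in the ΔNp73-labelled libraries. The labels do not say which exons the p53-null allele lacks. Neither difference from control passed the test (log2FC -1.61, SE 0.82, adjusted p = 0.455 and -0.92, SE 0.82, adjusted p = 0.537).

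Replicate 2 of the ΔNp63-labelled group stood apart from the other 7 libraries. Its median correlation with them across genes was 0.854, against 0.919 to 0.956 for the others, and 23.9% of its genes were over 2-fold from the rest of its group, against 1.49% to 6.68% elsewhere. Its correlation was higher with the controls (0.911 and 0.897) than with the other ΔNp63-labelled libraries (0.852 and 0.854). With the ΔNp73-labelled libraries it was 0.816, 0.844 and 0.865. Replicate 2 thus resembled the controls more than its own group by this measure. It had 142.9 FPKM of Cdkn2a, which encodes the tumour suppressors p16 and p19ARF, against at most 1.19 in any other library. Myc, a driver of growth, was at 92.3 FPKM against 15.4 to 21.7, and the transferrin receptor gene Tfrc at 122.4 against 8.61 to 19.3. Rag1, which recombines antigen receptor genes in immature thymocytes, was at 51.9 FPKM against 308 to 965, and Ptcra, the pre-T cell receptor chain, at 0.401 against 2.43 to 13.4. These 5 genes were chosen after their values were seen. The proliferation list in this library was 0.14 log2 units above the control mean, while the other ΔNp63-labelled libraries were at -1.83 and -1.81. Values without this library are therefore given beside those with it for the counts and for the lists in the ΔNp63-labelled group.

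**Figure D1:**
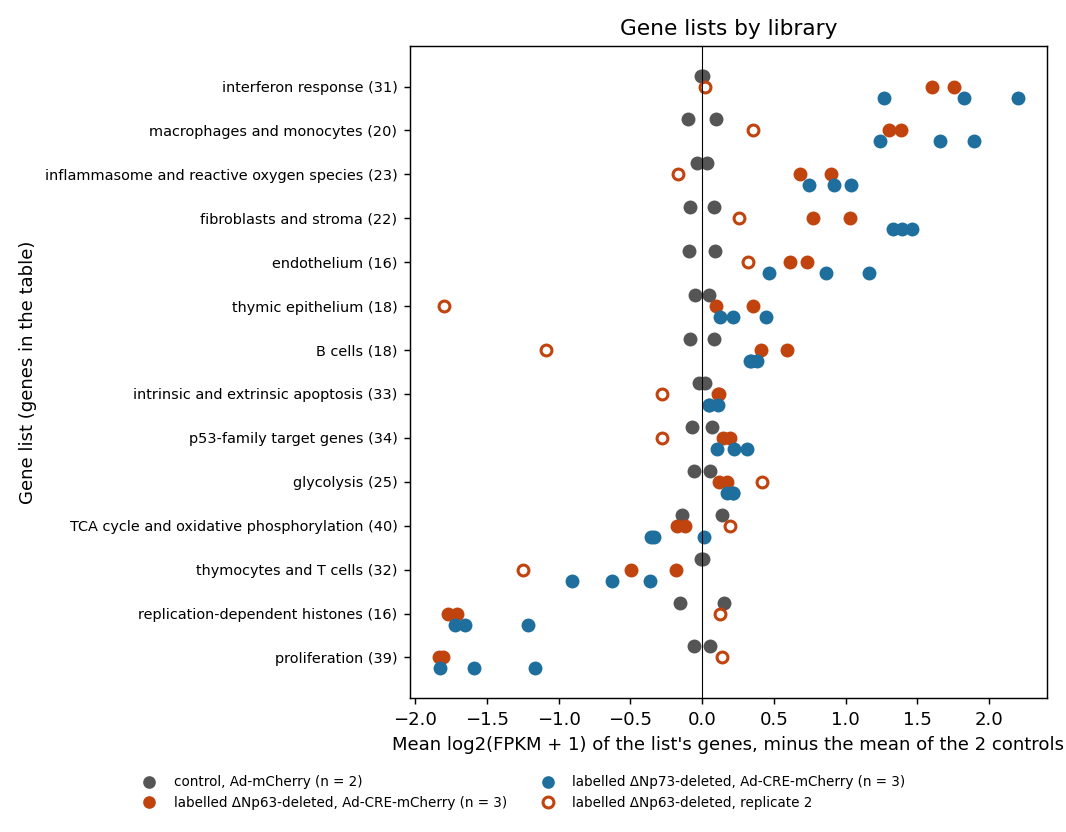
Mean log2(FPKM + 1) of each list's genes per library, minus the mean of the 2 controls, with 1 point per library; the open circle is ΔNp63-labelled replicate 2. In the interferon list that library is at 0.02, while the other 5 libraries of the deletion groups lie between 1.27 and 2.20.

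In the ΔNp63-labelled tumours the clearest changes were genes switched on or off as a group. H2-T10, a nonclassical MHC class I gene, rose from 0.298 ± 0.243 FPKM (SD, n = 2) to 32.3 ± 9.35 (SD, n = 3), a log2FC of 4.66 (SE 0.26, adjusted p = 0.000802). Ugt8a, which makes the myelin lipid galactosylceramide, rose from 0.0461 to 5.90 FPKM (log2FC 2.71, SE 0.17, adjusted p = 0.00148). Trim12a, a TRIM-family gene, fell from 10.7 to 0.257 FPKM (log2FC -3.22, SE 0.16, adjusted p = 0.000394), and Synpr, a synaptic vesicle gene, from 7.52 to 0.343 (log2FC -2.69, SE 0.25, adjusted p = 0.019). Each of these 4 genes had all 3 ΔNp63-labelled libraries on one side of the 5 others. All 4 are near 0 on one side, so their log2FC depend on the pseudocount and are smaller than the ratios of the printed means. Among the 100 genes with the smallest p in this comparison, 9 pairs were near neighbours of unrelated name, against 7 at the 95th percentile of random sets. Chromosome segments that differ between the mouse colonies may therefore account for part of these changes, as described further below.

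Of 12921 genes, 12 changed against control in the ΔNp63-labelled group, 4 higher and 8 lower, and 1678 had an unadjusted p under 0.05. Alox5ap, which presents arachidonic acid for leukotriene synthesis, also rose (log2FC 1.98, SE 0.20, adjusted p = 0.0233). The other falls among coding genes were Gfra1, a GDNF receptor (-2.54), the water channel gene Aqp11 (-2.19), Lynx1, a modulator of nicotinic receptors (-1.89), and the histone gene Hist2h2be (-1.63), with adjusted p from 0.0233 to 0.0459. The 3 small RNA genes among the 12 were Snora65, listed at 0 in every other group, and Snord15a and Rnu12, both lower. The count was 2882 (1497 higher, 1385 lower) without ΔNp63-labelled replicate 2, which included all 12 in the same direction. It was 3 without either control, 7 without ΔNp63-labelled replicate 1 and 7 without ΔNp73-labelled replicate 2, whose spread enters the shared model.

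Interferon and macrophage genes were called higher in the ΔNp63-labelled group as lists, and proliferation and histone genes lower, at the preset correlation alone. All 4 calls were lost with an estimated one (each adjusted p = 0.478 with an estimated correlation). All 31 interferon response genes lay above control (median log2FC 1.02, adjusted p = 7e-10), among them Oas1a (1.89, SE 0.37, adjusted p = 0.164), which senses double-stranded RNA, and Xaf1 (3.61, SE 0.71, adjusted p = 0.164). By limma 0 passed over all genes, 9 were higher at an unadjusted p under 0.05 and 2 rose adjusted over the list alone; without replicate 2 the median was 1.52 and 27 rose. All 19 macrophage and monocyte genes lay above control (median 1.06, adjusted p = 7e-10), such as the growth factor receptor gene Csf1r (1.08, SE 0.34, adjusted p = 0.285). Of these, 0 passed over all genes, 11 were higher at an unadjusted p under 0.05 and 2 rose adjusted over the list alone; without replicate 2 the median was 1.45 and 16 rose. All 39 proliferation genes lay below control (median -1.13, adjusted p = 5.5e-10), with Mki67 at -2.15 (SE 0.52, adjusted p = 0.219) and Ccnd3, the D cyclin of thymocytes, at -1.59 (SE 0.26, adjusted p = 0.131). Of these, 0 passed over all genes, 13 were lower at an unadjusted p under 0.05 and 1 fell adjusted over the list alone; without replicate 2 the median was -1.85 and all 39 fell. The 16 replication-dependent histones, which are made in S phase, were also all lower (median -1.23, adjusted p = 2.9e-05), 0 of them past the threshold with replicate 2 (3 lower at an unadjusted p under 0.05) and 12 without it (median -2.06).

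The fibroblast list was called higher (median 0.69, adjusted p = 3.9e-07), with 0 of 22 past the threshold over all genes, 9 higher at an unadjusted p under 0.05 and 6 risen adjusted over the list alone, such as the collagen gene Col1a2 (1.46, SE 0.23, adjusted p = 0.131 over all genes). This call and those of the 6 lists that follow were lost with an estimated correlation (each adjusted p = 0.478 with an estimated correlation). Endothelial genes (median 0.40, adjusted p = 0.00036), cytotoxic lymphocyte genes (0.57, adjusted p = 0.013), inflammasome genes (0.27, adjusted p = 0.0048), immediate early genes (0.31, adjusted p = 0.023) and ribosomal protein genes (0.17, adjusted p = 0.0033) were called higher as lists. The thymocyte list was lower (median -0.58, adjusted p = 1.2e-06), with 29 of 32 genes below control, such as Thy1 (-0.98, SE 0.21, adjusted p = 0.191). Adjusted over the list alone, 2 endothelial genes rose and 1 fell, 1 inflammasome and 1 immediate early gene rose, and none of the cytotoxic, ribosomal, thymocyte and histone genes passed. Of all 28 lists fry called 0. The ribosomal call was also lost without replicate 2 (median 0.08, adjusted p = 0.28). Under that setting the medians were 0.81 for fibroblasts (11 of 22 rose over all genes), 0.74 for the inflammasome (10 of 22 rose), 0.61 for immediate early genes (7 of 18 rose), 0.56 for endothelium (6 rose, 1 fell), 0.64 for cytotoxic lymphocytes (4 rose) and -0.41 for thymocytes (2 rose, 3 fell). The cytotoxic and immediate early calls were lost without replicate 1 or 3, and the inflammasome call without replicate 1.

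Other lists were not called in the ΔNp63-labelled group. The median was -0.09 for p53-family targets, -0.02 for apoptosis, 0.19 for senescence, 0.12 for glycolysis, -0.05 for the TCA cycle, 0.56 for amylin and its receptor, 0.23 for MYC and E2F-linked growth, -0.11 for the Notch pathway and -0.03 for epithelial and p63-linked genes. It was 0.32 for hypoxia, -0.12 for microRNA processing, 0.00 for B cells, 0.08 for neutrophils, -0.03 for dendritic cells, -0.10 for erythroid cells, -0.25 for thymic epithelium and 0.21 for adipocytes. Without replicate 2 it was 0.11 for p53-family targets, 0.19 for apoptosis, 0.06 for senescence, 0.13 for glycolysis, -0.16 for the TCA cycle, 0.17 for amylin and its receptor, -0.07 for MYC and E2F-linked growth and 0.05 for the Notch pathway. It was then 0.14 for hypoxia, -0.18 for microRNA processing, 0.39 for dendritic cells, -0.34 for erythroid cells, 0.24 for thymic epithelium and 1.21 for adipocytes. Casp2, an apoptotic caspase, was at -0.58 (SE 0.15, adjusted p = 0.236). Iapp, the gene of the peptide hormone amylin, was at 4.92 and 3.41 FPKM in the controls and at 11.2, 7.34 and 9.17 in the ΔNp63-labelled libraries (log2FC 0.99, SE 0.23, adjusted p = 0.212); without replicate 2 it rose (1.12, adjusted p = 0.0104). Of its receptor's partners, Ramp1 was at -0.09, Ramp2 at 0.56 and Ramp3 at 0.70, none past the threshold; without replicate 2, Ramp2 rose (0.73, adjusted p = 0.0313), while Ramp1 was at -0.15 and Ramp3 at 0.17 (adjusted p = 0.616). Ramp3 was at 10.3 FPKM in that library and at 2.78 and 2.66 in the others of its group. Without replicate 2, 2882 of 12782 genes passed in this comparison, so calls such as those of Iapp and Ramp2 are common there. B cell genes (0.58, adjusted p = 0.00029), neutrophil genes (0.54, adjusted p = 0.0078) and epithelial genes (0.27, adjusted p = 0.0045) were called higher without replicate 2, and not in the main model with all libraries. Their adjusted p was at least 0.293 with an estimated correlation. Epithelial genes were also called higher with array weights (median 0.24). Without replicate 2, fry called the apoptosis list higher (adjusted p = 0.0331), while camera did not.

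**Figure D2:**
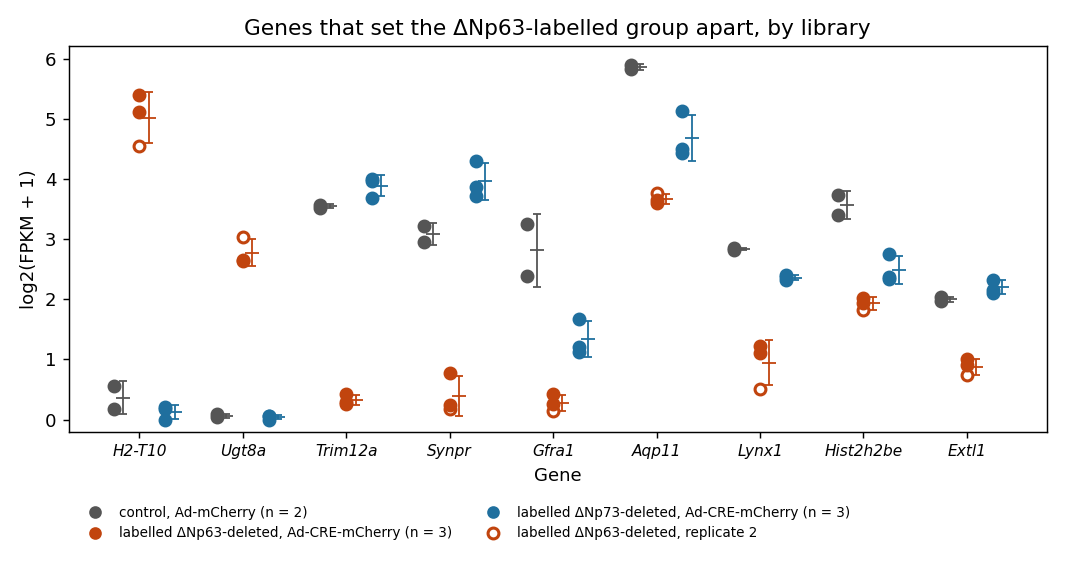
Values per library of 9 genes changed in the ΔNp63-labelled group or between the deletion groups, as log2(FPKM + 1); points are libraries and bars the mean and SD of each group. In H2-T10, Ugt8a, Trim12a and Synpr the 3 ΔNp63-labelled libraries, with replicate 2 as an open circle, lie apart from the other 5.

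In the ΔNp73-labelled tumours 6 coding genes rose against control. Alox5ap rose from 13.5 ± 1.29 FPKM (SD, n = 2) to 68.8 ± 14.7 (SD, n = 3), a log2FC of 2.25 (SE 0.20, adjusted p = 0.0289). Cysltr1, a receptor for cysteinyl leukotrienes, rose by 2.14 (SE 0.23, adjusted p = 0.0475), Col1a2 by 2.18 (SE 0.23, adjusted p = 0.0475) and the semaphorin receptor gene Plxnb2 by 1.60 (SE 0.14, adjusted p = 0.0289). Jun, an AP-1 subunit, rose by 1.56 and Clec7a, the beta-glucan receptor of myeloid cells, by 1.43, both with adjusted p = 0.0475. Each of the 6 was higher in 3 of 3 libraries than in both controls.

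These 6 genes and the small RNA Snord15a, which fell, were the 7 that changed of 12921, with 2747 at an unadjusted p under 0.05. The falls nearest the threshold did not pass (each adjusted p = 0.0597): Ctcf, the chromatin insulator gene (-1.06, SE 0.14), the germ cell genes Ybx2 (-1.60) and Tdrd5 (-1.26), Tmem151b (-1.63) and Ccdc153 (-1.83). The count was 4212 (2148 higher, 2064 lower) without ΔNp63-labelled replicate 2, which enters this comparison through the shared spread alone, and included all 7 in the same direction. It was 0 without control 1 (limma, 1066 at an unadjusted p under 0.05) and 0 without control 2 (1254), 1 without ΔNp73-labelled replicate 1 or 2, 2 without ΔNp73-labelled replicate 3, and 13 and 2 without ΔNp63-labelled replicates 1 and 3.

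Interferon, macrophage, fibroblast and neutrophil lists were called higher in the ΔNp73-labelled group at the preset correlation alone. These calls were lost with an estimated one (adjusted p = 0.410 for the first 3 and 0.420 for neutrophils with an estimated correlation). All 31 interferon genes lay above control (median 1.72, adjusted p = 1.9e-14); 0 passed over all genes, 25 were higher at an unadjusted p under 0.05 and 21 rose adjusted over the list alone, among them Oas1a (2.46, SE 0.37) and the nucleic acid sensor gene Zbp1 (2.18, SE 0.52), with adjusted p of 0.0676 and 0.1 over all genes. All 19 macrophage genes were higher (median 1.71, adjusted p = 1.5e-13), 0 passed over all genes, 17 were higher at an unadjusted p under 0.05 and 17 rose adjusted over the list alone, with Csf1r at 1.78 (SE 0.34) and the Fc receptor gene Fcgr3 at 2.27 (SE 0.33). All 22 fibroblast genes were higher (median 1.27, adjusted p = 6.4e-14); Col1a2 alone passed over all genes and 15 rose adjusted over the list alone, including Col1a1 (2.87, SE 0.35) and Col3a1 (2.42, SE 0.37). All 14 neutrophil genes were higher (median 1.19, adjusted p = 4.4e-05), with 0 past the threshold over all genes, 5 higher at an unadjusted p under 0.05 and 3 risen adjusted over the list alone, such as the chemokine receptor gene Cxcr2 (1.71, SE 0.27). Over all genes, 29 interferon, 18 macrophage, 19 fibroblast and 8 neutrophil genes rose without ΔNp63-labelled replicate 2.

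Endothelial genes (median 0.71, adjusted p = 1.4e-06), cytotoxic lymphocyte genes (1.10, adjusted p = 0.00027), inflammasome genes (0.85, adjusted p = 5.7e-05), immediate early genes (0.45, adjusted p = 0.00067) and epithelial and p63-linked genes (0.85, adjusted p = 2.1e-05) were also called higher. These calls were lost as well (adjusted p = 0.455 for the epithelial list and 0.410 for the others with an estimated correlation). Il1b, the cytokine that inflammasomes mature, was at 2.81 (SE 0.39, adjusted p = 0.0653), and Cdh3, the epithelial adhesion gene P-cadherin, at 1.18 (SE 0.36, adjusted p = 0.139). Adjusted over the list alone, 11 endothelial genes rose and 1 fell, 9 inflammasome genes rose and 1 fell, 3 cytotoxic and 7 immediate early genes rose, and no epithelial gene passed; over all genes Jun alone passed. Of the 21 epithelial genes, 13 rose without ΔNp63-labelled replicate 2.

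Proliferation genes were lower in the ΔNp73-labelled group, all 39 of them (median -1.58, adjusted p = 6.9e-12), as were thymocyte, histone and TCA cycle genes by their medians. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.455 for proliferation and thymocytes, 0.420 for histones and 0.761 for the TCA cycle with an estimated correlation). By limma 0 passed over all genes, 26 were lower at an unadjusted p under 0.05 and 1 fell adjusted over the list alone, Ccnd3 having the smallest p (-1.81, SE 0.26, adjusted p = 0.0653 over all genes); without ΔNp63-labelled replicate 2, 38 fell. The thymocyte list was lower (median -0.64, adjusted p = 1.1e-05), with 6 of 32 fallen adjusted over the list alone, 0 over all genes and 12 lower at an unadjusted p under 0.05, such as the T cell kinase gene Lck (-1.33, SE 0.21, adjusted p = 0.0676 over all genes). Without that library 15 fell and 1 rose. Histones (median -1.75, adjusted p = 7.5e-05; 2 fallen adjusted over the list alone, 0 over all genes and 8 at an unadjusted p under 0.05) and the TCA cycle list (-0.25, adjusted p = 0.012; 0 in either count and 1 at an unadjusted p under 0.05) were lower. The TCA cycle call was also lost without control 2 or ΔNp73-labelled replicate 2 or 3. Of the 28 lists fry called 1, fibroblasts (adjusted p = 0.044).

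Lists not called in the ΔNp73-labelled group were p53-family targets (median 0.07), apoptosis (0.15), senescence (0.30), glycolysis (0.12), amylin and its receptor (0.23), hypoxia (0.28), MYC and E2F-linked growth (-0.15), the Notch pathway (-0.04), microRNA processing (-0.07), ribosomal proteins (0.03), B cells (0.44), dendritic cells (0.48), erythroid cells (-1.49), thymic epithelium (0.17) and adipocytes (-0.57). Adjusted over the list alone, 5 senescence genes rose, among them the cytokine gene Il1a (0.80, SE 0.18, adjusted p = 0.0963 over all genes). Casp8, the initiator caspase of death receptors, was at 0.61 and the glycolytic gene Hk3 at 1.62, neither past the threshold. Iapp was at 8.40, 5.94 and 7.68 FPKM in the ΔNp73-labelled libraries (log2FC 0.70, SE 0.23, adjusted p = 0.162), and Trp63 at a log2FC of 1.08 (SE 0.67, adjusted p = 0.382). Ramp1 (-0.56, adjusted p = 0.125), Ramp2 (0.85, adjusted p = 0.119) and Ramp3 (0.23, adjusted p = 0.812) did not pass. Without ΔNp63-labelled replicate 2, Iapp (adjusted p = 0.0279), the highest entry of Trp63 (0.0394) and Ramp2 (0.00969) rose and Ramp1 fell (0.0171). Under that setting 4212 of 12782 genes passed, so such calls are common. Camera then also called the B cell list (adjusted p = 0.0084, and 0.368 with an estimated correlation). Fry, and not camera, then called apoptosis (adjusted p = 0.0457), glycolysis (0.0292) and dendritic cells (0.0457) higher.

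**Figure D3:**
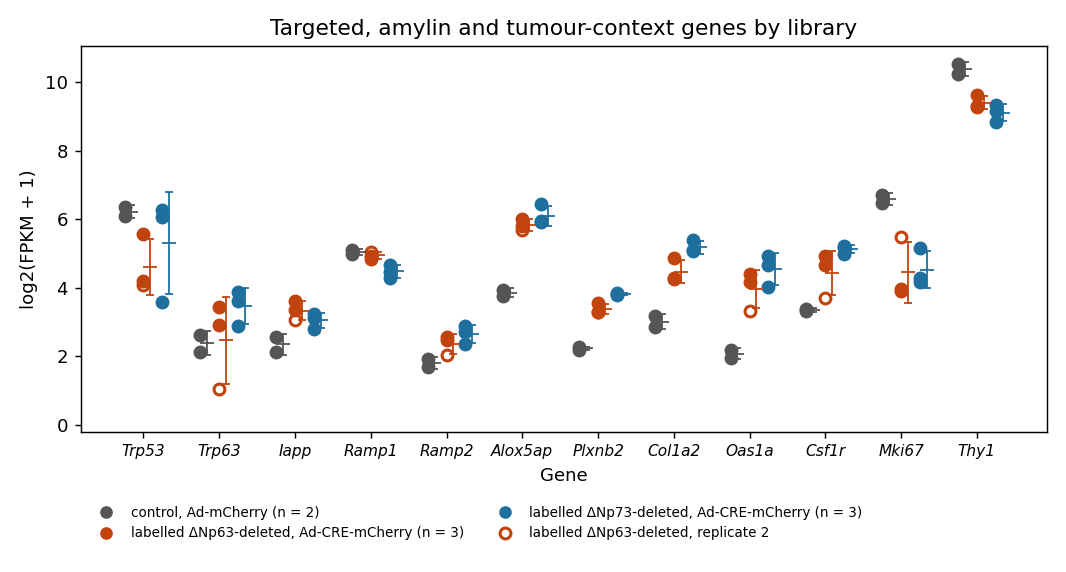
Values per library of the targeted, amylin and selected named genes, as log2(FPKM + 1); points are libraries, the open circle is ΔNp63-labelled replicate 2 and bars are the mean and SD of each group. Alox5ap lies at 14.4 and 12.6 FPKM in the controls and between 50.8 and 85.7 in the other 6 libraries.

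Taking the mean of both deletion groups against control, 15 genes changed, 10 higher and 5 lower. In 4 of the 15 the deletion libraries overlapped the controls, so a call here need not be a change common to both groups. Alox5ap rose by 2.12 (SE 0.18, adjusted p = 0.0203), Ncf4, a subunit of the phagocyte NADPH oxidase, by 1.91 (SE 0.23, adjusted p = 0.0465), Col1a2 by 1.82, Cysltr1 by 1.71, Plxnb2 by 1.37, Clec7a by 1.31 and Jun by 1.26. Aqp11 (-1.69, SE 0.20), Ybx2 (-1.61, SE 0.19) and Ctcf (-1.04, SE 0.12) fell, each with adjusted p = 0.0465. Alox5ap and Snord15a were the 2 genes changed in both comparisons, Alox5ap higher in 6 of 6 libraries than in both controls. Snord15a was at 22.3 and 41.4 FPKM in the controls and listed at 0 in the other 6 libraries. As lists, interferon (median 1.32), macrophage (1.35) and fibroblast genes (0.98) were higher and proliferation genes lower (-1.36), with adjusted p of 9.2e-14, 4.1e-13, 2.2e-12 and 1.5e-12 in that order. With an estimated correlation no list was called (lowest adjusted p = 0.420 with an estimated correlation).

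The changes of the 2 groups against control correlated across genes with r = 0.73, against a mean of 0.60 in simulated draws without any effect. In each draw both groups shared 2 simulated controls, and every library had the same spread in a gene. The real controls lay close together (r = 0.972), while ΔNp63-labelled replicate 2 lay far from its group. The simulated r is therefore not a matched baseline for the observed one. Genes are not independent replicates, and the 2 controls cannot be split. Without ΔNp63-labelled replicate 2, r was 0.84 against a simulated 0.54 and 2368 genes changed in both comparisons, 1273 higher and 1095 lower, where independent lists would share 251.6 and 223.6; 7 changed in opposite directions. Under that setting the mean of both groups gave 4194 changed genes in place of 15. The mean gave 0 without control 1 (limma, 818 at an unadjusted p under 0.05) and 0 without control 2 (928), 6 and 3 without ΔNp63-labelled replicates 1 and 3, and 3, 2 and 6 without ΔNp73-labelled replicates 1, 2 and 3; the shared count was 0 without either control and 1 without ΔNp73-labelled replicate 1 or 2.

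Compared directly, where both had received Cre, the 2 deletion groups differed in a small set of genes with large folds. H2-T10 was lower in the ΔNp73-labelled group (log2FC -4.89, SE 0.23, adjusted p = 0.000333), as was Ugt8a (-2.74, SE 0.15, adjusted p = 0.000615), and Trim12a (3.56, SE 0.14, adjusted p = 0.000113), Synpr (3.56, SE 0.23, adjusted p = 0.00137) and Extl1, a gene of the exostosin family (1.32, SE 0.14, adjusted p = 0.0392), were higher. Trim12a was at 10.7 FPKM in control, 0.257 in the ΔNp63-labelled and 13.9 in the ΔNp73-labelled group, and Synpr at 7.52, 0.343 and 14.8. Among the 100 genes with the smallest p, 12 pairs were near neighbours of unrelated name. In all 7 genes differed of 12921, the others being Snora65 and Rnu12; without ΔNp63-labelled replicate 2 the count was 19, which included all 7. Dzip1 (2.17, SE 0.25, adjusted p = 0.0645), the cell surface genes Ly6k (-4.05, SE 0.61, adjusted p = 0.185) and Psca (-2.44, SE 0.37, adjusted p = 0.185), Lynx1 (1.42) and Xlr4b (-0.93) did not pass; without that library Ly6k, Psca, Lynx1 and Xlr4b did.

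Iapp, Ramp1, Ramp2 and Ramp3 did not differ by the test between the deletion groups, with log2FC of -0.29, -0.47, 0.29 and -0.48, nor did Trp63 (means of 5.84 FPKM in the ΔNp63-labelled and 10.5 in the ΔNp73-labelled group, adjusted p = 0.52). Leaving out ΔNp63-labelled replicate 2, these were -0.43, -0.41, 0.12 and 0.06, so that Ramp3 turned its sign, with 0.28 for Trp63, again none past the threshold. Of 28 lists 17 were called, the largest medians being neutrophils (1.15, adjusted p = 1e-05) and epithelial and p63-linked genes (0.97, adjusted p = 2.5e-08), both higher in the ΔNp73-labelled group. All 17 calls were lost with an estimated correlation (adjusted p of at least 0.736 with an estimated correlation), and fry called 0 lists. Lamb3 (1.15, SE 0.31, adjusted p = 0.421) and Cxcr2 (0.92, SE 0.24, adjusted p = 0.421) are examples that did not pass. The preset correlation called 7 lists without ΔNp63-labelled replicate 2. Under that setting fibroblasts (0.54), epithelial genes (0.47), neutrophils (0.54) and macrophages (0.28) were higher in the ΔNp73-labelled group, thymocytes (-0.31) and adipocytes (-1.89) lower, and proliferation, which was lower with all libraries (-0.35), was higher (0.32), each with adjusted p = 0.862 with an estimated correlation.

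The other 6 lists had too few measured members for a test. The median log2FC in the ΔNp63-labelled and ΔNp73-labelled groups was -0.76 and 0.08 for the targeted genes (2 measured), 0.14 and 0.97 for platelets and megakaryocytes (4), -0.32 and -0.20 for muscle (3), 0.40 and 0.09 for lung and airway epithelium (2), 0.21 and 0.18 for pancreas (4), and -1.81 and -0.61 for sex-linked genes (4). The sign of the median, the mean and the test differed for 3 lists in the ΔNp63-labelled comparison, 1 in the ΔNp73-labelled, 1 in their mean and 3 between the deletion groups, none of them called.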

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

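The tests of explanations in the last 3 paragraphs of this part were chosen after the result was seen, while the gene tests, the list tests and the counts over other splits of the 6 libraries were planned. The results listed first are differences between the 2 deletion groups that passed their test. As log2 fold changes of the ΔNp73-labelled over the ΔNp63-labelled group, Trim12a (3.56), Synpr (3.56), Extl1 (1.32) and the small nuclear RNA Rnu12 (3.75) were higher, and H2-T10 (-4.89), Ugt8a (-2.74) and the small nucleolar RNA Snora65 (-8.17) were lower. Snora65 was listed at 0 in all control and ΔNp73-labelled libraries, so its value depends on the pseudocount and is no fold.

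Of the 28 lists, 17 differed between the deletion groups by camera with its preset correlation and 0 with an estimated one (adjusted p of at least 0.736 with an estimated correlation). The medians of the lists higher in the ΔNp73-labelled group were 1.15 for neutrophils, 0.97 for epithelial and p63-linked genes, 0.79 for thymic epithelium, 0.67 for the interferon response, 0.66 for fibroblasts, 0.55 for macrophages, 0.48 for cytotoxic lymphocytes, 0.46 for B cells, 0.44 for the inflammasome, 0.44 for dendritic cells, 0.40 for immediate early genes, 0.28 for endothelium and 0.20 for p53-family targets. Those lower were MYC and E2F-linked growth (-0.37), proliferation (-0.35), the TCA cycle (-0.17) and ribosomal proteins (-0.13). Leaving out ΔNp63-labelled replicate 2, 7 lists were called, and the medians of proliferation (0.32), MYC and E2F-linked growth (0.00317), B cells (-0.12) and thymic epithelium (-0.00276) changed sign. The others then were 0.54 for neutrophils, 0.47 for epithelial genes, 0.12 for interferon, 0.54 for fibroblasts, 0.28 for macrophages, 0.21 for cytotoxic lymphocytes, 0.04 for the inflammasome, 0.06 for dendritic cells, 0.03 for immediate early genes, 0.23 for endothelium, 0.06 for p53-family targets, -0.08 for the TCA cycle and -0.03 for ribosomal proteins. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7 genes and no other split more than 1, so 1 of 10 gave as many. For lists, the real split gave 17, the highest other 21, and 3 of the 10 gave as many. The split with 21 set ΔNp63-labelled replicate 1 and ΔNp73-labelled replicates 1 and 2 against the rest.

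Replicate 2 of the ΔNp63-labelled group stood apart from the other libraries. A library of another group under a wrong label is argued against by single genes: 24 genes separated the other 2 libraries of its group from the 5 libraries outside it, and for 15 of them (62.5%) replicate 2 lay on the side of its own group. Such genes may mark the mouse colony, so they do not show which virus the tumour received. Across genes it correlated more with the controls (0.911 and 0.897) than with its own group (0.852 and 0.854). Less non-tumour tissue of an unchanged mix would lower the genes of the other cell types alike. Thymic epithelium genes were lower by 1.33 log2 units more than endothelial genes (difference of the medians -1.33, two-sided permutation p = 0.0008), which argues against an even loss as the sole reason. The permutation exchanged genes, which are not independent replicates, so this p does not measure the spread between tumours. An uneven loss of non-tumour cells is not excluded. Gains and losses of whole chromosomes may be part of why replicate 2 stood apart. The chromosomes' median differences spanned 0.87 log2 units in this library and 0.17 at most in any other. In 1000 random assignments of genes to chromosomes they spanned 0.35 at most. After each chromosome's median was taken out, 23.9% of the genes used stayed over 2-fold from its group, from 26.0% before. That step removes only the average shift of a chromosome. It therefore cannot decide whether gains and losses account for the whole distance.

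Interferon, macrophage, fibroblast, endothelial and cytotoxic lists were called higher than in control in both deletion groups at the preset correlation, and none of them with an estimated one (adjusted p of at least 0.410 with an estimated correlation). A lower share of tumour cells with an unchanged mix of the other cells would raise their markers alike. In the ΔNp73-labelled group macrophage genes exceeded thymic epithelium genes by a median of 1.53 log2 units (two-sided permutation p = 1e-05, the smallest that the draws can give). The permutation exchanged genes, which are not independent replicates, so this p does not measure the spread between tumours. The gap argues only against an even rise as the sole reason. A lower tumour share in which the mix also differs is not excluded. A rise of the macrophages themselves or of their activity stays open. The Cre virus and the deletions cannot be told apart, because no control received Cre; the groups' changes correlated across genes with r = 0.84 without ΔNp63-labelled replicate 2, and shared controls alone give a positive r.

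Of the genes that separate the deletion groups, H2-T10, Ugt8a, Trim12a and Synpr were nearly on or off. Chromosome segments that differ between the mouse colonies from their breeding may account for part of the separating genes: among the 100 genes with the smallest p there were 12 pairs of near neighbours of unrelated name, against 9 in the ΔNp63-labelled and 4 in the ΔNp73-labelled comparison with control, a mean of 3.72 in 10000 random sets, and 7 at their 95th percentile. There were 16 pairs without ΔNp63-labelled replicate 2. Names were judged by the first letters of the symbol alone, so related genes under different names also count, and the pairs are not specific to inherited segments. Reads of Trim12a assigned to its copy Trim12c are argued against, since Trim12c was also lower where Trim12a was near 0 (log2FC 1.28, SE 0.27). Whether reads of H2-T10 were assigned to its relatives H2-T9 and H2-T22, or theirs to it, is left open, as their sum differed by -0.13 (SE 0.42), which does not decide. A direct effect of the deletions was not tested.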

How the results depend on the processing

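All alternatives were planned. No paired analysis was possible because the labels give no replicate numbers or pairs. Leaving out ΔNp63-labelled replicate 2, and array weights, which give that library a weight of 0.0567, raised every count of changed genes. Leaving out 1 library at a time, the count ranged from 3 to 2882 in the ΔNp63-labelled comparison (12 with all libraries), from 0 to 4212 in the ΔNp73-labelled (7), from 0 to 4194 in their mean (15), from 6 to 19 between the deletion groups (7) and from 0 to 2368 for genes changed in both (2). The lowest values came without a control, which leaves 1 control assumed to vary like the other groups, except for the 6, which came without ΔNp63-labelled replicate 1 or 3 or ΔNp73-labelled replicate 2 or 3. Array weights gave 4480, 6569, 6296, 344 and 3626 in that order. A model of the compared groups alone gave 3 in the ΔNp63-labelled comparison, 3856 in the ΔNp73-labelled, which then lacks the ΔNp63-labelled libraries, and 1 gene in both. For the ΔNp73-labelled comparison a pseudocount of 0.1 gave 18, a pseudocount of 0.5 gave 11 and robust empirical Bayes 3. An adjusted p under 0.1 gave 449 there, 217 for the mean and 9 in both, and empirical Bayes without trend gave 9 for the mean. The cause was not tested, except where fewer libraries or a looser threshold are the alternative itself. The other alternatives, including both scalings, left each count within 1.5 times. Of 333 gene results, 6220 alternative values comprised 5572 on the same side of the threshold, 179 that lost the call, 469 that gained it and 0 reversed.

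Of 112 list results, 2344 alternative values comprised 2122 on the same side, 159 lost, 55 gained and 8 reversed. With array weights the reversed medians were 0.242 for epithelial and p63-linked genes in the ΔNp63-labelled comparison and, between the deletion groups, 0.221 for proliferation, 0.0206 for MYC and E2F-linked growth and -0.113 for B cells. Leaving out 1 library, the same medians ranged from -0.264 to 0.273, from -0.667 to 0.324, from -0.574 to 0.00317 and from -0.125 to 0.738, the reversed end each time without ΔNp63-labelled replicate 2. No list was called with an estimated correlation (lowest adjusted p of 0.478, 0.410, 0.420 and 0.736 over the comparisons; 11, 13, 12 and 17 called with the preset one), and fry called 0, 1, 0 and 0. Without ΔNp63-labelled replicate 2, fry called 9, 14, 13 and 0. The depth is unknown, so what it limits cannot be stated; few libraries, 2 of them controls, limit the precision.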

Other observations

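The test on chromosomes below was chosen after the result was seen. Fat and muscle genes varied between single tumours of the same group. The genes of these 2 paragraphs were chosen after their values were seen, from the fixed lists except Gbp1. Fabp4, a lipid carrier of fat cells and macrophages, was at 103.3 and 683.1 FPKM in the controls, at 1630, 63.3 and 1145 in the ΔNp63-labelled libraries and at 2086, 155.9 and 153.2 in the ΔNp73-labelled libraries, and Adipoq, which encodes the fat cell hormone adiponectin, at 6.12 and 40.9, at 61.1, 3.76 and 40.5, and at 68.3, 5.27 and 3.48. Muscle genes marked a single library, ΔNp73-labelled replicate 1: Mb (myoglobin) was at 43.2 FPKM there and at most 0.381 elsewhere, and Ckm (muscle creatine kinase) at 4.68 and at most 0.526. The Y-linked gene Ddx3y was at 17.3 FPKM in control 1 and at 21.4 in ΔNp73-labelled replicate 1, and at most 0.0692 in the other 6 libraries, so Y-linked expression is not balanced between the groups.

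The blood gene Hbb-b1 and the platelet gene Pf4 followed the groups in part, without passing the threshold. The erythroid list did not share the pattern of Hbb-b1. Its median log2FC was -0.10 in the ΔNp63-labelled group, with 3 of 7 genes higher than control and 4 lower. In the ΔNp73-labelled group it was -1.49, with 1 higher and 6 lower. The haemoglobin gene Hbb-b1 was at 26.0 and 136.1 FPKM in the controls, at 3.07, 0.0338 and 2.35 in the ΔNp63-labelled and at 32.5, 19.99 and 13.1 in the ΔNp73-labelled libraries (log2FC of the ΔNp63-labelled group -4.66, SE 0.82, adjusted p = 0.158), lower in all 3 than in the 5 others. Pf4, platelet factor 4, was at 3.86 and 5.29 in the controls, 93.4, 8.32 and 14.2 in the ΔNp63-labelled and 69.5, 36.1 and 30.4 in the ΔNp73-labelled libraries, higher in all 6 than in both controls. The guanylate-binding protein gene Gbp1 was at 0.141 and 0.0526 in the controls, at 14.8, 3.87 and 16.6 in the ΔNp63-labelled and at 0.238, 0.292 and 5.66 in the ΔNp73-labelled libraries (log2FC of the ΔNp63-labelled group 3.34, SE 0.83, adjusted p = 0.222).

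In ΔNp63-labelled replicate 2, cell type lists lay below the rest of its group, by medians of -1.79 for thymic epithelium, -1.74 for interferon genes, -1.66 for neutrophils, -1.60 for B cells, -1.26 for dendritic cells, -1.13 for macrophages, -0.94 for fibroblasts, -0.74 for thymocytes, -0.46 for endothelium and -0.46 for cytotoxic lymphocytes, and proliferation (1.97) and MYC and E2F-linked growth (1.09) lay above. A hypothesis is that this tumour carries gains and losses of whole chromosomes, which the range of 0.87 log2 units between the chromosomes' medians may reflect. Of 20 chromosomes 5 had a median over 0.2, each positive both before and after its middle gene, and 6 a median under -0.2, each negative on both sides (lowest -0.36). Among the higher ones were those that carry Rb1 (0.51), Kit (0.30), Cdkn2a (0.26) and Myc (0.24). DNA copy number was not analysed here.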
